A study of Mus musculus with 34 samples.

How the data were processed

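RNA was sequenced from frozen whole prostates, with extraction by the Nucleospin RNA II kit, per the labels' protocols. Tumour groups received tamoxifen by gavage on 4 days and controls the vehicle, per the labels' protocols. The genome build was mm9 and R 2.11.1 was used, per the labels. The aligner, the counting, the annotation and the normalization are not stated. The deposited table holds 14063 lines and 34 library columns of log2 values. The base and unit were worked out from the values. In 33 columns, 2 to the power of the value times the exonic length of the gene in kilobases summed to between 0.964 and 1.20 times the total that RPKM implies, where base e gave 8.47 to 21.9 times, so these deposited values were taken as log2 RPKM. Exonic lengths were matched for 98.5% of the lines. Of these 33 libraries, 32 had nearly equal quartiles (lower quartile 0.887 to 1.16), for which no method is stated, and luminal 1 month 2 a wider spread (0.0589). The table gives no counts, so the depth is unknown, no counting interval can be given, and values for genes with few reads run down to -49.7 (18.0% of values lay below 0).

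Columns were checked for order in runs of 250 lines. In each run the ranks of a library were correlated with the mean ranks of the other libraries on the common scale. Luminal control 4 was on another scale, per the deposited values, with a sum 3032 times that total and 505 lines at its lowest value. From line 12716 on its values were also misplaced (of 984 above its lowest value, 91.9% repeated earlier lines of the column, 99.6% in their order). It was left out of the main analysis, although the plan fixed before the data were examined had all 34 libraries in the model. In luminal 3 months 5 the values from line 12287 on did not belong to their genes: 65.7% of these 1777 values repeated earlier lines of the column, 100% in the order of those lines. From 10 lines before that point its values were set to missing, for 1781 genes. Of 67 symbols with more than 1 line, 1 line each was kept and 113 were dropped, which left 13950 genes. Another 20 names had been turned into dates by a spreadsheet. Near-identical genes that may share reads, such as Sbp and Sbpl, are uncertain.

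Groups were taken from the labels. A linear model with the 6 groups as levels was fitted to 33 libraries with limma 3.58.1 in R 4.3.3 (moderated statistics with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over 13950 genes and a threshold of 0.05. The filter on low values removed 0 genes. Gene lists, 33 in number and fixed beforehand from textbook knowledge of prostate cell types, other cells and pathways, were tested on 32 libraries, without luminal 3 months 5, with limma's camera at a preset correlation of 0.01. They were tested again with an estimated correlation and with fry, with adjustment over the lists of a comparison. Pten, Nkx3-1 and Krt5 were also compared by exact permutation tests over 24 comparisons. Other tests, figures and sums used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

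The genes named follow a rule fixed with the plan. Among genes past the threshold with an official symbol, and with every library of one group on the same side of the other group's mean, it takes the 8 largest changes each way in the first 5 comparisons and the 5 largest in the other 4, where the higher group lies above the median level of 3.00. It adds the 2 to 4 members with the smallest p of at most 8 called lists, and always gives Pten, Nkx3-1, Krt5, Krt14, Trp63, Krt8, Krt18, Ar, Pbsn and Mki67 with leading seminal vesicle and immune markers. The text gives a part of the genes the rule takes.

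The gene test was run on simulated basal tumours at 3 months and controls (13950 genes, drawn independently). Of genes changed by 0.5, 1 and 2 (log2) it called 52.9% of 68, 78.8% of 66 and 93.9% of 66. It called 6 unchanged genes (3.85% of calls), and 0 where nothing differed. The list test called the 1 raised list and 0 of 20 unchanged lists, but correlated genes were not tested. Alternatives were quantile normalization, median centring, no filter, a stricter filter, no intensity trend, library weights, only the compared groups, the replicate number as a block, and leaving out each library in turn. A further 5, such as leaving out 4 vesicle-high libraries (Ceacam10 above 9), were chosen after seeing the data, and the planned fit of all 34 libraries was run beside them.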

Results

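Transcript levels were measured by RNA sequencing in whole prostates of C57BL/6 mice that carried 2 floxed alleles of Pten, a phosphatase gene that restrains PI3K signalling. Tamoxifen switched on a Cre recombinase in basal cells (the CK5-CreERT2 line, called basal) or in luminal cells (the Nkx3.1-CreERT2 line, called luminal), so that Pten was deleted from a chosen cell of origin. The basal line gave 6 control libraries, 5 libraries from tumours at 3 months and 6 from tumours at 6 months after induction. The luminal line gave 5 control libraries, of which 4 could be used, and 6 libraries each from tumours at 1 month and at 3 months. Mice were induced at 2 months of age and controls, given vehicle, were 5 months old, so that only the tumours at 3 months matched their controls in age. The values of the libraries used were taken as log2 RPKM, a read density scaled for gene length and library size, as their sums imply, and 13950 genes were compared. A difference of 1 is 2-fold. The table gives no read counts, so the depth of each library is unknown. Levels are given as mean ± SD over the libraries of a group, and changes as log2 difference ± SE from limma with Benjamini-Hochberg adjusted p-values. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these samples, which may be technical in part. In the comparisons with controls, each gene said to have risen or fallen did so in every tumour library against the control mean, apart from Serpine2, which did so in 4 of 6 basal libraries at 6 months.

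Pten was lower in every tumour group than in its controls, though far from absent. Its level was 4.76 ± 0.090 in basal controls (n = 6), 4.26 ± 0.071 in basal tumours at 3 months (n = 5) and 4.20 ± 0.072 at 6 months (n = 6), with an exact two-sided permutation p of 0.00216 for either time, the smallest these groups allow. In the luminal line it was 4.89 ± 0.15 in controls (n = 4), 4.61 ± 0.19 at 1 month (n = 6, exact p = 0.0333) and 4.30 ± 0.16 at 3 months (n = 6, exact p = 0.00476, the smallest possible). At 1 month Pten was 4.73 to 4.79 in libraries 1 to 3 and 4.33 to 4.64 in 4 to 6. The fall at 1 month did not pass in limma once each library was centred on its median (-0.19, adjusted p = 0.093). The labels do not say which exons are floxed, and the prostate holds cells in which Cre is not active, so this level checks the labels only in part. Nkx3-1, the homeobox gene whose locus carries the Cre allele in the luminal line, stood at 8.15 ± 0.22 in luminal controls and 8.64 ± 0.21 in basal controls (exact p = 0.019, adjusted p = 0.0305 over 24 such tests). That difference of -0.48 did not pass in limma (adjusted p = 0.54, and 0.0264 with only the compared groups). Nkx3-1 fell in all tumour groups, by 4.65 ± 0.47 and 7.32 ± 0.45 in the basal line and by 5.18 ± 0.50 and 6.74 ± 0.50 in the luminal line. Krt5, the keratin gene whose promoter drives Cre in the basal line, rose in all 4 tumour groups, by 2.16 ± 0.19, 1.72 ± 0.19, 2.68 ± 0.21 and 2.05 ± 0.21 in the same order.

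**Figure D1:**
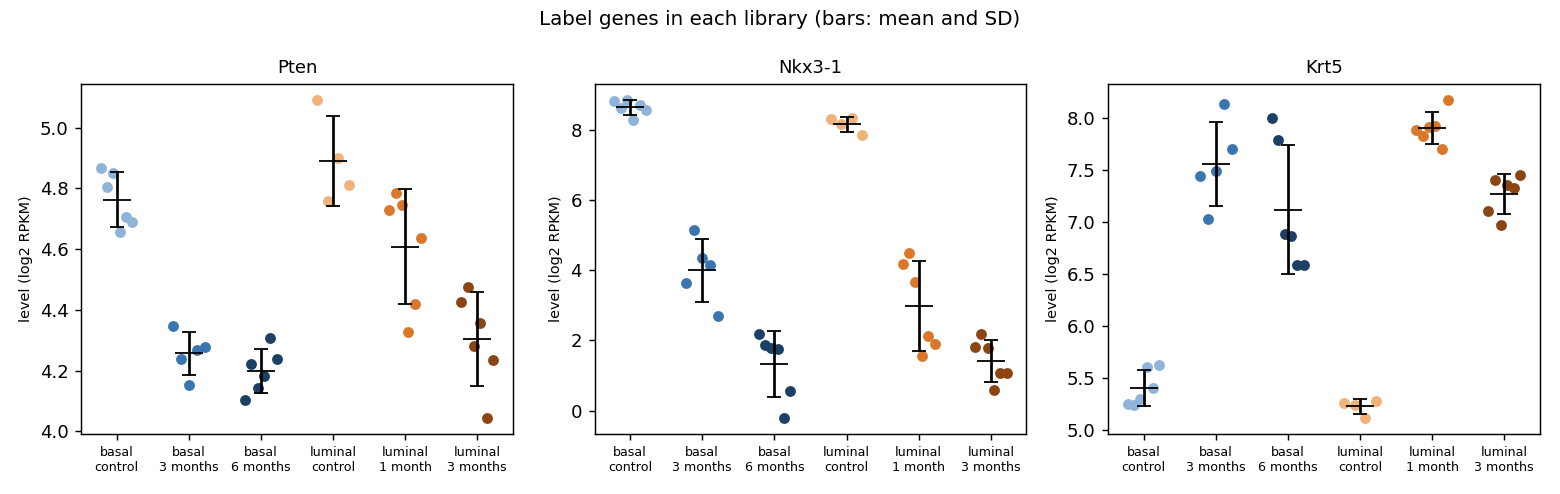
Levels of Pten, Nkx3-1 and Krt5 in each library (points, log2 units on the vertical axis) by group, with the group mean and SD as bars. Nkx3-1 lies above 7 in every control library used and was lower in each tumour group, with a mean of 1.32 in basal tumours at 6 months and 1.41 in luminal tumours at 3 months.

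Basal tumours at 3 months were compared with basal controls of the same age, which asks how the prostate differs once Pten has been deleted in basal cells. By camera, lists of progenitor-like, interferon response, glycolysis and cell cycle genes were higher in these tumours. Of all list calls by camera in the 9 comparisons, that of the progenitor-like list here was the only one kept with an estimated correlation. Among the largest rises, Nupr1, a stress-induced nuclear protein, went from 4.27 ± 1.53 to 11.27 ± 0.32. Wfdc2, a secreted protein with protease inhibitor domains, went from 4.26 ± 1.17 to 11.11 ± 0.41. Pglyrp1, which binds bacterial peptidoglycan, went from 3.00 ± 0.93 to 9.53 ± 0.38. Among the largest falls, Nkd1, an inhibitor of Wnt signalling, went from 4.68 ± 0.25 to -1.85 ± 0.97. Aass, an enzyme of lysine breakdown, went from 4.47 ± 0.19 to -1.71 ± 1.11. C1rb, a complement protease gene, went from 10.33 ± 0.29 to 4.55 ± 0.99.

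All 13 progenitor-like and proximal luminal markers rose (13 also adjusted over the list alone, here list-adjusted, camera adjusted p = 1.48e-10, 0.0436 at estimated correlation). Ly6a, which encodes Sca-1, rose by 5.41 ± 0.18, Tacstd2, which encodes Trop2, by 4.67 ± 0.22, and the chaperone gene Clu by 5.97 ± 0.30. All 20 interferon response genes rose, 20 also list-adjusted (camera adjusted p = 3.04e-10, 0.389 at estimated correlation). Ifit1 rose by 4.81 ± 0.30 and Oas1a by 4.04 ± 0.30. Of 17 glycolysis and hypoxia genes 16 rose, 16 also list-adjusted (camera adjusted p = 6.45e-09, 0.174 at estimated correlation). The glycolytic enzyme genes Pfkl and Pkm2 rose by 1.98 ± 0.10 and 2.14 ± 0.10. Of 22 cell cycle genes 21 rose, 21 also list-adjusted (camera adjusted p = 1.47e-07, 0.434 at estimated correlation), among them Birc5, needed for chromosome segregation, by 4.26 ± 0.39 and Mki67, the proliferation marker, by 3.28 ± 0.36. Of 14 chemokine and cytokine genes 12 rose, 13 list-adjusted (camera adjusted p = 0.000167, 0.27 at estimated correlation). The neutrophil attractant Cxcl5 rose by 5.41 ± 0.49 and Tnf by 4.64 ± 0.41.

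Among 16 basal cell markers 10 rose and 1 fell, as they did list-adjusted (camera adjusted p = 0.000972, 0.434 at estimated correlation). Krt15 rose by 4.83 ± 0.27 and Krt14 by 2.23 ± 0.32, whereas Trp63, the transcription factor gene of basal cells, differed by 0.33 ± 0.23 and did not pass (adjusted p = 0.203). Squamous and keratinization genes rose in 7 of 10 cases, 7 also list-adjusted (camera adjusted p = 0.01, 0.27 at estimated correlation). Of 12 immediate early genes, which also respond to handling of the tissue, 10 rose and 1 fell, as they did list-adjusted (camera adjusted p = 0.01, 0.649 at estimated correlation). Ier3 rose by 2.35 ± 0.18 and Junb by 1.53 ± 0.14. Of 15 unfolded protein response genes 12 fell, 12 also list-adjusted (camera adjusted p = 0.003, 0.649 at estimated correlation), among them the chaperone genes Pdia6 by 1.91 ± 0.15 and Creld2 by 2.32 ± 0.23. The luminal keratin Krt8 rose by 1.98 ± 0.12 and the androgen receptor gene Ar by 1.23 ± 0.17, while Krt18 differed by 0.19 ± 0.092 (adjusted p = 0.0665), by -0.059 after quantile normalization, and passed after median centring (0.0377) and without basal control 5 (0.0439) or basal 3 months 4 (0.0413). Pbsn, the probasin gene of secretory cells, fell by 3.20 ± 0.79. Of the markers of other cells, Ctss and C1qa of macrophages rose by 2.16 ± 0.29 and 1.16 ± 0.28, the T cell kinase gene Lck fell by 2.38 ± 0.22, Cd3d differed by -0.87 ± 0.44 (adjusted p = 0.0852), and of the seminal vesicle genes Serpine2 fell by 2.93 ± 0.97 and Spinkl differed by 2.91 ± 2.02 (adjusted p = 0.205). With only the compared groups Trp63 and Spinkl passed (adjusted p = 0.0342 and 0.00394), Cd3d did with library weights (0.0314) or without basal control 4 (0.00205), and Spinkl (0.0422) without 4 libraries of other groups high in a seminal vesicle gene (called vesicle-high: basal 6 months 2 and 3, luminal 1 month 5, luminal 3 months 5). All 5 blood cell genes fell, 5 also list-adjusted, although the list did not pass (camera adjusted p = 0.135).

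In total, 9221 of 13950 genes passed adjusted p 0.05, 4035 higher and 5186 lower, and 2134 were at least 2-fold higher and 1828 at least 2-fold lower. The median over all genes of the log2 difference was -0.12 here and -0.13 for basal tumours at 6 months, so small falls in these 2 comparisons lie close to that shift. The luminal and basal lines each had their own controls, and no library counts in both.

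**Figure D2:**
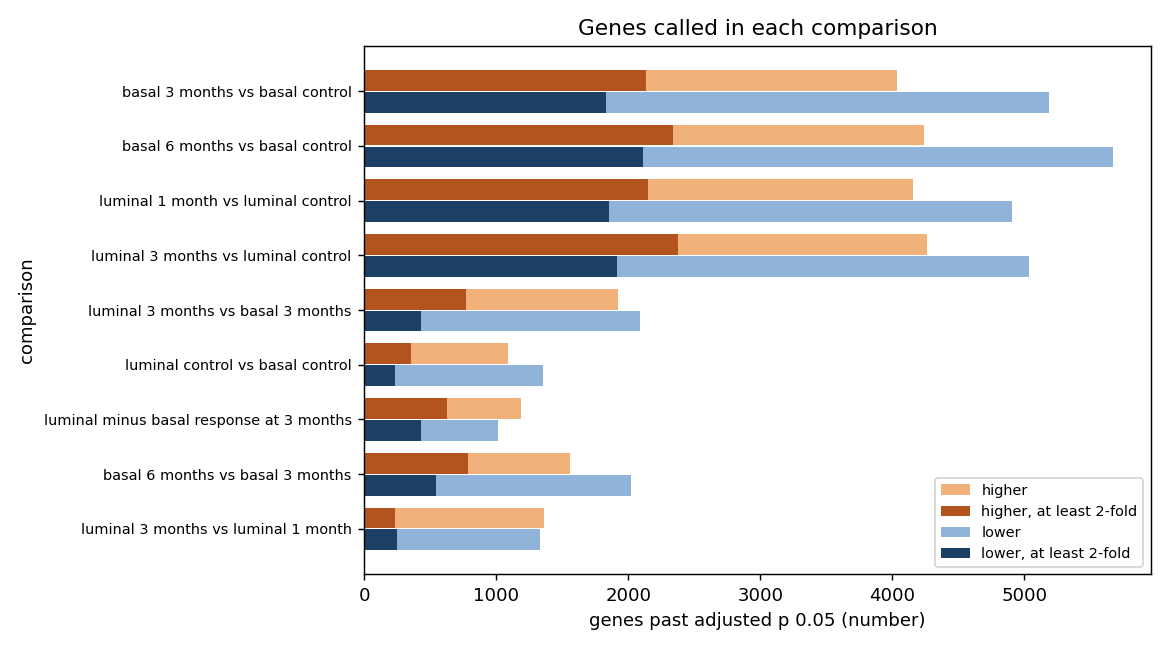
Number of genes past adjusted p 0.05 in each comparison (bars from 0, higher and lower genes apart), with the part that differed at least 2-fold in darker shade. The counts run from 2194 for the difference between the responses of the lines to 9915 for basal tumours at 6 months against controls.

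Basal tumours at 6 months were compared with the same basal controls, which were about 3 months younger, to show the later stage of this line. Among the largest rises, Reg3g, a bactericidal lectin, went from 0.40 ± 1.62 to 10.69 ± 2.08. Ltf, which encodes the iron-binding lactotransferrin, went from 0.20 ± 0.80 to 9.72 ± 0.76, and the mucin gene Muc1 from -2.30 ± 0.80 to 5.72 ± 0.51. Nkx3-1 was among the largest falls, and Gsdma2, a gasdermin gene, went from 3.81 ± 0.21 to -4.26 ± 1.10. Mcoln3, a lysosomal cation channel gene, went from 4.48 ± 0.19 to -3.09 ± 1.11.

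All 20 interferon response genes rose, 20 also list-adjusted (camera adjusted p = 1.16e-09, 0.492 at estimated correlation). Ifit1 rose by 4.88 ± 0.29 and the GTPase gene Gbp2 by 3.58 ± 0.24. All 13 progenitor-like and proximal luminal markers rose, 13 also list-adjusted (camera adjusted p = 1.47e-09, 0.0777 at estimated correlation). Tacstd2 rose by 4.97 ± 0.21 and Krt7 by 5.20 ± 0.23. Glycolysis and hypoxia genes rose in 15 of 17 cases, 15 also list-adjusted (camera adjusted p = 1.21e-07, 0.183 at estimated correlation), among them the hypoxia-induced Egln3 by 5.38 ± 0.32. Chemokine and cytokine genes rose in 13 of 14 cases, 13 also list-adjusted (camera adjusted p = 2.94e-05, 0.183 at estimated correlation). Cxcl5 rose by 7.83 ± 0.47 and Csf1, the macrophage growth factor, by 2.24 ± 0.14. Complement and secreted defence genes rose in 10 of 11 cases, 11 list-adjusted (camera adjusted p = 0.00011, 0.183 at estimated correlation). Lcn2 rose by 6.51 ± 0.30 and Pigr, which carries antibodies into secretions, by 5.92 ± 0.27.

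Macrophage and monocyte markers rose in 12 of 14 cases, 12 also list-adjusted (camera adjusted p = 0.000671, 0.584 at estimated correlation). Ctss rose by 3.35 ± 0.27, Mrc1 by 3.07 ± 0.32 and C1qa by 2.26 ± 0.26. MHC class II genes rose in 7 of 8 cases, 7 also list-adjusted (camera adjusted p = 0.00794, 0.584 at estimated correlation). Basal cell markers rose in 11 of 16 cases and 1 fell, also list-adjusted (camera adjusted p = 0.00101, 0.584 at estimated correlation). Krt15 rose by 4.41 ± 0.26 and Krt14 by 2.43 ± 0.31. Unfolded protein response genes fell in 13 of 15 cases and 1 rose, also list-adjusted (camera adjusted p = 0.00182, 0.584 at estimated correlation). Pdia6 changed by -2.39 ± 0.14. Immediate early genes rose in 7 of 12 cases and 1 fell (camera adjusted p = 0.0516, and 0.0432 after quantile normalization) and smooth muscle markers fell in 7 of 12 and 1 rose (camera adjusted p = 0.421), the same counts as list-adjusted. Cell cycle genes rose in 14 of 22 cases and 1 fell, 13 and 1 list-adjusted (camera adjusted p = 0.0115, 0.719 at estimated correlation), and Mki67 rose by 1.5 ± 0.35. The 10 luminal cell markers went both ways, 6 up and 3 down (also list-adjusted), with a median of 0.47, a mean of -0.43 and no call (camera adjusted p = 0.411, direction up). Within them Krt8 rose by 1.91 ± 0.11, Ar rose by 1.19 ± 0.16, and Krt18 differed by 0.029 ± 0.087 (adjusted p = 0.775), a value that turned to -0.29 (adjusted p = 0.00143) after quantile normalization. Pbsn fell by 4.88 ± 0.75. Trp63 differed by 0.16 ± 0.22 (adjusted p = 0.523) and Cd3d by 0.76 ± 0.42 (adjusted p = 0.108), while Lck fell by 1.04 ± 0.21. Cd3d passed with library weights (0.0169) and without basal control 1 (0.0181), basal 6 months 2 (0.0396) or the vesicle-high libraries (0.0249). Spinkl rose by 7.51 ± 1.92 with a spread of 5.02 between libraries, and Serpine2 fell by 3.16 ± 0.93.

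In this comparison 9915 genes passed, 4241 higher and 5674 lower, of which 2342 and 2110 differed at least 2-fold. The controls are shared with the comparison at 3 months. In both, 7875 genes were called in the same direction and 63 in opposite directions, against 3336 for independent lists. The log2 differences correlated across genes with r = 0.881 and covariance 1.82, where simulated unchanged groups against the same controls gave a mean r of 0.431 and covariance of 0.0485. With the 6 controls split into 3 and 3 in 20 ways, r lay between 0.756 and 0.861, the covariance between 1.68 and 1.79, and the shared calls between 6644 and 6990. Genes are not independent replicates.

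Luminal tumours at 1 month (n = 6) were compared with luminal controls (n = 4), which were 2 months older, to show the early stage of this line. In camera calls lost at an estimated correlation, lists of secretory proteins were lower and of interferon response genes higher. Tgm4, the prostate transglutaminase gene, fell from 12.43 ± 0.46 to 3.84 ± 1.79. Pbsn went from 13.64 ± 0.62 to 5.18 ± 2.02 (6.56 to 7.55 in libraries 1 to 3 and 2.69 to 4.60 in 4 to 6). Azgp1 went from 8.75 ± 0.19 to 1.04 ± 0.50. Krt6a, a keratin of stressed epithelium, rose from -1.72 ± 0.94 to 4.85 ± 0.87. Ido1, which breaks down tryptophan, went from -1.44 ± 0.90 to 4.69 ± 0.55. Padi4, which converts arginine in proteins to citrulline, went from -0.10 ± 0.77 to 6.24 ± 0.12.

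All 20 interferon response genes rose, 20 also list-adjusted (camera adjusted p = 2.12e-13, 0.263 at estimated correlation). Ifit1 rose by 5.69 ± 0.32 and Rtp4 by 4.38 ± 0.26. Progenitor-like and proximal luminal markers rose in 12 of 13 cases, 12 also list-adjusted (camera adjusted p = 1.03e-08, 0.115 at estimated correlation). Ly6a rose by 4.70 ± 0.19 and Clu by 5.33 ± 0.32. Glycolysis and hypoxia genes rose in 16 of 17 cases, 16 also list-adjusted (camera adjusted p = 1.03e-06, 0.263 at estimated correlation). Pkm2 rose by 1.90 ± 0.11. Chemokine and cytokine genes rose in 13 of 14 cases, 13 also list-adjusted (camera adjusted p = 5.84e-05, 0.263 at estimated correlation). Cxcl10, an interferon-induced attractant of T cells, rose by 5.72 ± 0.47. Cell cycle genes rose in 20 of 22 cases, 20 also list-adjusted (camera adjusted p = 7.13e-05, 0.666 at estimated correlation). Birc5 rose by 3.00 ± 0.41 and Mki67 by 2.17 ± 0.39. Complement and secreted defence genes rose in 9 of 11 cases, 9 also list-adjusted (camera adjusted p = 0.00102, 0.263 at estimated correlation). Lcn2 rose by 5.42 ± 0.34.

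Prostate secretory proteins fell in 7 of 9 cases, 7 also list-adjusted (camera adjusted p = 0.00352, 0.263 at estimated correlation). Unfolded protein response genes fell in 12 of 15 cases and 1 rose, 13 and 1 list-adjusted (camera adjusted p = 0.00346, 0.666 at estimated correlation). Sdf2l1 changed by -2.46 ± 0.20. Macrophage and monocyte markers rose in 12 of 14 cases, 13 list-adjusted (camera adjusted p = 0.00115, 0.666 at estimated correlation). Ctss rose by 2.61 ± 0.31 and C1qa by 1.86 ± 0.29. MHC class II genes rose in 7 of 8 cases, 7 also list-adjusted (camera adjusted p = 0.0175, 0.666 at estimated correlation). Basal cell markers rose in 10 of 16 cases and 1 fell, the same counts as list-adjusted (camera adjusted p = 0.00383, 0.635 at estimated correlation). Krt14 rose by 1.45 ± 0.35. Trp63 was higher by 0.88 ± 0.24 (adjusted p = 0.00219), but by 0.54 (adjusted p = 0.0634) with luminal control 6, luminal 1 month 2 and luminal 3 months 5 all left out. Krt8 rose by 1.54 ± 0.13 and Ar by 1.23 ± 0.18. Krt18 was higher by 0.26 ± 0.10 (adjusted p = 0.0189), a call lost after quantile normalization (0.13, adjusted p = 0.202). It was also lost without luminal control 1, 2 or 6, or luminal 1 month 4 (0.0779, 0.0506, 0.053 and 0.0674). So it was with only the compared groups (0.105) and without those 3 libraries (0.0515). Lck fell by 1.35 ± 0.23, while Cd3d (0.70 ± 0.47), Serpine2 (-1.48 ± 1.03) and Spinkl (0.055 ± 2.15) did not pass (adjusted p = 0.194, 0.212 and 0.984), though Serpine2 passed without the vesicle-high libraries (-1.96, adjusted p = 0.000863). The 5 blood cell genes all fell, 5 also list-adjusted, with no call for the list (camera adjusted p = 0.125). In all, 9070 genes passed, 4160 higher and 4910 lower, of which 2153 and 1855 differed at least 2-fold. More were higher than lower after median centring (4622 and 4267) and among genes above the median level (2572 and 2525).

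Luminal tumours at 3 months (n = 6) were compared with luminal controls of the same age (n = 4), which asks how the prostate differs once Pten has been deleted in luminal cells. Lists of interferon response, glycolysis and progenitor-like genes were higher, in camera calls lost at an estimated correlation. Among the largest falls, Glb1l3, a gene related to beta-galactosidase, went from 8.96 ± 0.40 to -2.99 ± 1.05 (n = 5). Tgm4 went from 12.43 ± 0.46 to 3.05 ± 1.00 (n = 5). Pnliprp1, a pancreatic lipase relative, went from 7.98 ± 0.44 to -2.21 ± 1.21. Among the largest rises, Nos2, the inducible nitric oxide synthase gene, went from -3.64 ± 0.89 to 3.09 ± 0.36, and the interferon-induced Ifi202b from -0.78 ± 1.33 to 5.83 ± 0.80. Wfdc2 went from 6.24 ± 0.99 to 12.71 ± 0.13. A value with n = 5 leaves out luminal 3 months 5, whose values could not be assigned to 1781 of the genes.

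All 20 interferon response genes rose, 20 also list-adjusted (camera adjusted p = 8.66e-13, 0.348 at estimated correlation). Ifit1 rose by 5.86 ± 0.32 and Irf1 by 2.20 ± 0.15. All 17 glycolysis and hypoxia genes rose, 17 also list-adjusted (camera adjusted p = 4.57e-10, 0.106 at estimated correlation). Pfkl rose by 2.13 ± 0.10 and Aldoa by 1.74 ± 0.10. Progenitor-like and proximal luminal markers rose in 12 of 13 cases, 12 also list-adjusted (camera adjusted p = 2.33e-08, 0.106 at estimated correlation). Ly6a rose by 4.80 ± 0.19 and Krt7 by 3.83 ± 0.25. Chemokine and cytokine genes rose in 13 of 14 cases, 13 also list-adjusted (camera adjusted p = 5.69e-06, 0.106 at estimated correlation). Cxcl10 rose by 6.23 ± 0.47 and Ccl20 by 5.98 ± 0.52. Complement and secreted defence genes rose in 8 of 11 cases, 8 also list-adjusted (camera adjusted p = 0.00258, 0.407 at estimated correlation). Ltf rose by 6.21 ± 0.48 (n = 5). Cell cycle genes rose in 17 of 22 cases, 17 also list-adjusted (camera adjusted p = 0.00365, 0.778 at estimated correlation), and Mki67 rose by 1.41 ± 0.39.

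Macrophage and monocyte markers rose in 12 of 14 cases, 13 list-adjusted (camera adjusted p = 0.000181, 0.587 at estimated correlation). Ctss rose by 3.09 ± 0.31, Aif1 by 2.53 ± 0.30 and C1qa by 2.19 ± 0.29. MHC class II genes, which present antigen, rose in 7 of 8 cases, 7 also list-adjusted (camera adjusted p = 0.00364, 0.6 at estimated correlation). Cd74 rose by 2.38 ± 0.33 and H2-Ab1 by 2.01 ± 0.33. Unfolded protein response genes fell in 14 of 15 cases, 14 also list-adjusted (camera adjusted p = 1.42e-05, 0.568 at estimated correlation). Sdf2l1 changed by -3.12 ± 0.20. Smooth muscle markers fell in 11 of 12 cases, 11 also list-adjusted (camera adjusted p = 0.0175, 0.778 at estimated correlation). Ribosome biogenesis genes fell in 9 of 15 cases, 9 also list-adjusted (camera adjusted p = 0.0175, 0.587 at estimated correlation). Prostate secretory proteins fell in 6 of 9 cases and 1 rose, also list-adjusted (camera adjusted p = 0.0272, 0.568 at estimated correlation). Basal cell markers rose in 10 of 16 cases and 1 fell, 10 and 2 list-adjusted (camera adjusted p = 0.0162, 0.645 at estimated correlation). Krt14 (5.77 to 6.22) was higher by 1.06 ± 0.35 (adjusted p = 0.00809). Without luminal control 1 it was so by 0.77 (0.0648), without 2 by 0.70 (0.0805).

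Krt8 rose by 1.55 ± 0.13, Ar by 1.34 ± 0.19 (n = 5), and Pbsn fell by 8.71 ± 0.87 (n = 5). Krt18 was higher by 0.25 ± 0.10 (adjusted p = 0.0258), a call lost after quantile normalization (0.050, adjusted p = 0.628). It was also lost without luminal control 1, 2 or 6 (0.0982, 0.0646 and 0.0683) or the 3 libraries named above (0.0807). Trp63 (0.44 ± 0.24), Lck (-0.31 ± 0.23) and Spinkl (1.16 ± 2.15) did not pass (adjusted p = 0.11, 0.234 and 0.644), although Trp63 passed without luminal control 1 (0.70, adjusted p = 0.0124), and Serpine2 fell by 3.68 ± 1.03. Cd3d, with a level of 0.18 ± 0.19 (n = 5), was higher by 1.46 ± 0.49 (adjusted p = 0.0101), a call lost once values below 0 were raised to 0 (0.20, adjusted p = 0.374). In this comparison 9301 genes passed, 4266 higher and 5035 lower, of which 2376 and 1912 differed at least 2-fold. It shares its controls with the comparison at 1 month. Both called 7752 genes in the same direction and 26 in opposite directions, against 3044 for independent lists. The log2 differences had r = 0.932 and covariance 1.86 across genes, against a simulated mean of 0.596 and 0.0795 with no effect. With the 4 controls split into 2 and 2 in 6 ways, r lay between 0.836 and 0.879, the covariance between 1.74 and 1.81 and the shared calls between 6112 and 6328.

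The responses at 3 months of the basal and luminal lines, which share no library, went in the same direction for most genes called in both. Of these, 3196 were higher and 4034 lower in both lines, against 1234 and 1872 for independent lists, and 151 were called in opposite directions against 3042. Across genes the log2 differences correlated with r = 0.816 and had a covariance of 1.67. Simulated unchanged groups gave a mean r of -0.04 (highest 0.193) and a mean covariance of -0.0056.

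**Figure D3:**
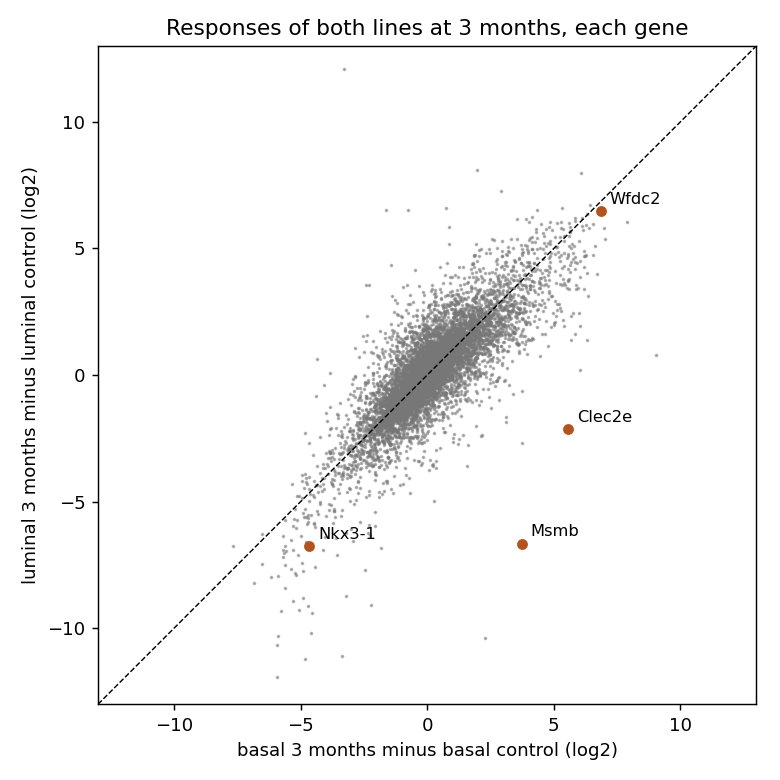
Log2 difference of each of 13950 genes in luminal tumours at 3 months against luminal controls (vertical axis) and in basal tumours at 3 months against basal controls (horizontal axis), each point being a gene. Points gather along the rising diagonal (r = 0.816 across genes), and the named genes Clec2e and Msmb lie far below it.

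Luminal tumours were compared with basal tumours at 3 months (n = 6 and 5), the same time after induction and the same age, which asks whether the cell of origin leaves a difference. Lists of MHC class II, T and NK cell and macrophage genes were higher in luminal tumours and that of secretory proteins lower by camera, but not at an estimated correlation. Olfm4, a secreted glycoprotein of mucosal epithelium, stood at 5.96 ± 1.26 in luminal and -2.47 ± 1.36 in basal tumours, Slco1a5, an organic anion transporter gene, at 6.17 ± 0.12 and 1.59 ± 0.95, and Muc1 at 6.16 ± 0.47 and 2.40 ± 0.92. Clec2e, a lectin-like receptor gene, was -1.41 ± 0.45 in luminal and 5.24 ± 0.21 in basal tumours, Msmb, a secretory protein of the prostate, 1.64 ± 2.30 and 8.86 ± 1.57, and Pbsn 4.93 ± 1.80 (n = 5) and 10.24 ± 1.15.

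All 8 MHC class II genes were higher in luminal tumours, 8 also list-adjusted (camera adjusted p = 4.99e-07, 0.174 at estimated correlation). Cd74 was higher by 1.86 ± 0.31 and H2-DMa by 1.5 ± 0.23. T and NK cell markers were higher in 13 of 14 cases, 13 also list-adjusted (camera adjusted p = 7.55e-07, 0.174 at estimated correlation). Lck was higher by 1.69 ± 0.22 and Cd8b1 by 2.21 ± 0.41. Macrophage and monocyte markers were higher in 11 of 14 cases, 13 list-adjusted (camera adjusted p = 2.75e-06, 0.346 at estimated correlation). Tyrobp was higher by 1.57 ± 0.33, Ctss by 1.25 ± 0.29 and C1qa by 1.22 ± 0.28. Among 3 neutrophil markers 2 were higher, 2 also list-adjusted (camera adjusted p = 0.0109, 0.174 at estimated correlation). Interferon response genes were higher in 14 of 20 cases, 16 list-adjusted (camera adjusted p = 8.04e-06, 0.549 at estimated correlation). Gbp2 was higher by 1.18 ± 0.25 and Irf7 by 1.35 ± 0.36. Chemokine and cytokine genes were higher in 10 of 14 cases, 10 also list-adjusted (camera adjusted p = 0.000156, 0.174 at estimated correlation). Il1b was higher by 2.32 ± 0.39. Complement and secreted defence genes were higher in 8 of 11 cases and lower in 1, also list-adjusted (camera adjusted p = 0.000729, 0.199 at estimated correlation). C3 was higher by 2.28 ± 0.48.

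Prostate secretory proteins were lower in luminal tumours in 5 of 9 cases, 5 also list-adjusted (camera adjusted p = 0.00127, 0.174 at estimated correlation). Azgp1 changed by -3.12 and Tgm4 by -5.14 on the log2 scale. Unfolded protein response genes were lower in 10 of 15 cases, 10 also list-adjusted (camera adjusted p = 0.000177, 0.549 at estimated correlation). Pdia6 stood at 7.13 ± 0.068 against 8.03 ± 0.22. Cell cycle genes were lower in 5 of 22 cases, 5 also list-adjusted (camera adjusted p = 0.0088, 0.772 at estimated correlation). Mki67 stood at 1.98 ± 0.085 against 3.11 ± 0.19. Luminal cell markers were lower in 4 of 10 cases, 4 also list-adjusted (camera adjusted p = 0.0156, 0.174 at estimated correlation). Nkx3-1 stood at 1.41 ± 0.60 against 3.99 ± 0.91. Endothelial markers were higher in 7 of 11 cases, 7 also list-adjusted (camera adjusted p = 0.0259, 0.549 at estimated correlation), and blood cell genes in 4 of 5, 4 also list-adjusted (camera adjusted p = 0.0469, 0.549 at estimated correlation). The keratins and their regulators did not separate the tumours. The differences were -0.29 ± 0.19 for Krt5, -0.32 ± 0.32 for Krt14, -0.23 ± 0.23 for Trp63, -0.16 ± 0.12 for Krt8, -0.059 ± 0.092 for Krt18, -0.040 ± 0.18 for Ar and 0.047 ± 0.080 for Pten, none past adjusted p 0.05 (lowest 0.269 for Krt5). With library weights Krt5 passed (-0.39, adjusted p = 0.0294), and Krt8 passed with only the compared groups in the model (adjusted p = 0.0377). Spinkl (3.12 ± 2.02) and Serpine2 (-1.57 ± 0.97) did not pass (adjusted p = 0.254 and 0.23), though Serpine2 passed with library weights (0.0246) and without the vesicle-high libraries (-2.12, adjusted p = 0.00086). Cd3d was higher by 1.65 ± 0.46 (adjusted p = 0.00756), and by 0.20 (adjusted p = 0.458) once values below 0 were raised to 0. The comparison called 4009 genes, 1922 higher and 2087 lower in luminal tumours, of which 772 and 428 differed at least 2-fold, and with library weights 6927.

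**Figure D4:**
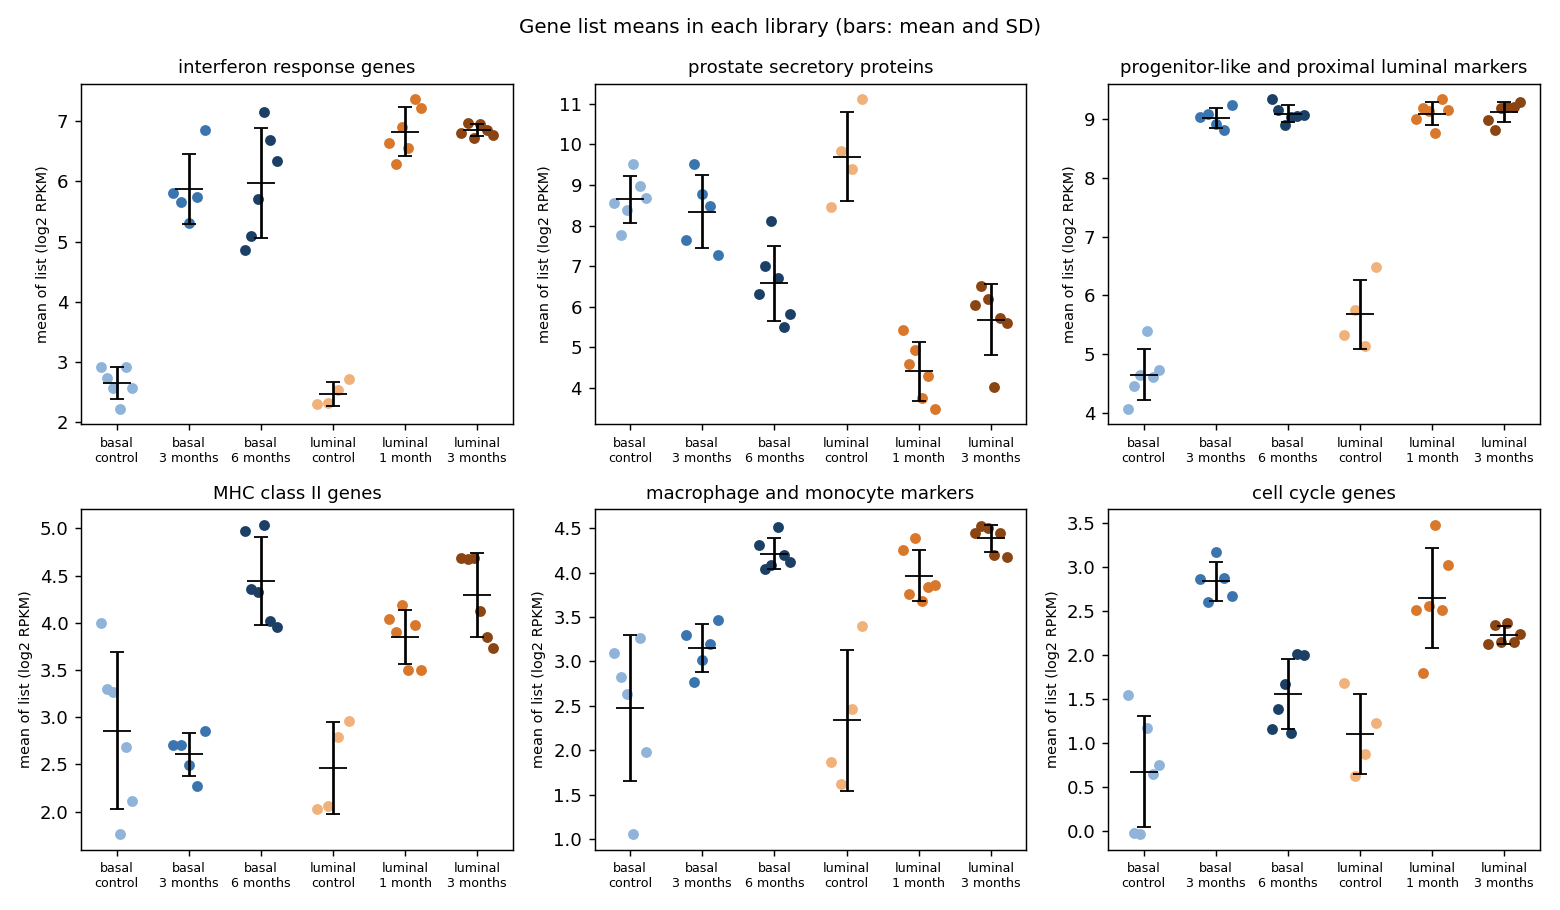
Mean level of 6 gene lists in each library (points, log2 units) by group, with the group mean and SD as bars. MHC class II genes averaged 2.61 in basal tumours at 3 months and 4.30 in luminal tumours at 3 months, and cell cycle genes 2.83 and 2.22.

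Luminal controls (n = 4) were compared with basal controls (n = 6), which shows how the lines differ without induction. The list of progenitor-like genes was higher in luminal controls and that of cholesterol synthesis genes lower, in camera calls lost at an estimated correlation. Camk2b, a calmodulin-dependent kinase gene, stood at 5.62 ± 0.28 in luminal and -2.44 ± 1.47 in basal controls, Reg3g at 5.06 ± 1.48 and 0.40 ± 1.62, and Gdpd3, a phosphodiesterase gene, at -0.48 ± 0.72 and 6.20 ± 0.22. Aim2, a sensor of cytosolic DNA, was 1.45 ± 0.73 in luminal and 4.03 ± 0.17 in basal controls.

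Progenitor-like and proximal luminal markers were higher in luminal controls in 8 of 13 cases, 10 list-adjusted (camera adjusted p = 7.31e-06, 0.405 at estimated correlation). Krt7 was higher by 1.53 ± 0.25 and Tacstd2 by 1.16 ± 0.24. Immediate early genes were higher in 6 of 12 cases, 7 list-adjusted (camera adjusted p = 0.000267, 0.489 at estimated correlation). The list averaged 3.93 and 3.74 in luminal controls 5 and 6 but 2.38 and 2.52 in 1 and 2, beside 2.14 to 2.50 in basal controls. Nr4a1 was higher by 1.14 ± 0.26 and Ier2 by 0.61 ± 0.14. Cholesterol synthesis genes were lower in 8 of 18 cases, 10 list-adjusted (camera adjusted p = 0.00311, 0.734 at estimated correlation). In basal controls the list averaged 2.91 to 3.06 in 1 to 3 and 3.54 to 3.69 in 4 to 6. Luminal controls had 2.82 to 2.92. The receptor gene Ldlr stood at 1.69 ± 0.22 against 3.30 ± 0.46. Ribosome biogenesis genes were higher in 5 of 15 cases, 6 list-adjusted (camera adjusted p = 0.00311, 0.489 at estimated correlation). Gnl3 was higher by 0.81 ± 0.13. Genes of p53 and senescence were higher in 4 of 13 cases, 6 list-adjusted (camera adjusted p = 0.0089, 0.489 at estimated correlation). Gdf15 was higher by 1.89 ± 0.24. Of 12 smooth muscle markers 2 were higher, 2 also list-adjusted (camera adjusted p = 0.0089, 0.734 at estimated correlation). Smtn was higher by 1.16 ± 0.21. Of 22 cell cycle genes 2 were higher, 1 list-adjusted (camera adjusted p = 0.011, 0.769 at estimated correlation). Ube2c was higher by 1.31 ± 0.33. Of 14 T and NK cell markers 3 were higher, 3 also list-adjusted (camera adjusted p = 0.0433, 0.734 at estimated correlation). Gzmb was higher by 1.65 ± 0.39. Krt5 (-0.18 ± 0.21), Krt14 (0.85 ± 0.35), Trp63 (-0.34 ± 0.24), Krt8 (0.26 ± 0.13), Krt18 (-0.12 ± 0.10), Ar (-0.15 ± 0.18), Pbsn (0.20 ± 0.84), Mki67 (0.74 ± 0.39) and Pten (0.13 ± 0.085) did not pass, and Krt14 passed without luminal control 1 (adjusted p = 0.0328) or 2 (adjusted p = 0.0159). Nor did Ctss (0.32 ± 0.31), C1qa (0.20 ± 0.29), Lck (-0.38 ± 0.23), Serpine2 (-0.82 ± 1.03), Spinkl (4.87 ± 2.15) or Cd3d (-0.67 ± 0.47), although Spinkl passed without luminal control 1 (adjusted p = 0.0445) or the vesicle-high libraries (0.0117) and Cd3d without basal control 4 (adjusted p = 0.0429). With only the compared groups Serpine2, Spinkl and Krt8 passed (adjusted p = 0.00355, 0.0226 and 0.0471). The comparison called 2439 genes, 1088 higher and 1351 lower, of which 357 and 229 differed at least 2-fold. Without luminal control 6 the count was 1481.

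The difference between the responses of the lines at 3 months, luminal minus basal, was tested as an interaction, which takes out what the lines differ by without induction. In camera calls lost at an estimated correlation, lists of MHC class II and interferon response genes were higher in this difference, and those of secretory and cell cycle genes lower. Muc20, a mucin gene, went from 1.55 ± 0.50 to 5.07 ± 0.23 in the luminal line and from 3.40 ± 0.31 to 3.08 ± 0.59 in the basal line. Msmb went from 8.30 ± 2.79 to 1.64 ± 2.30 in the luminal line and from 5.12 ± 2.27 to 8.86 ± 1.57 in the basal line. Luminal controls 2 and 6 had a mean Msmb level of 10.67 and luminal controls 1 and 5 one of 5.92. Clec2e went from -0.33 ± 0.93 to 5.24 ± 0.21 in the basal line and from 0.73 ± 1.30 to -1.41 ± 0.45 in the luminal line, and Camk2b from 5.62 ± 0.28 to -4.75 ± 0.87 in the luminal line and from -2.44 ± 1.47 to -0.14 ± 3.28 in the basal line. Camk2b had a mean of 3.43 in basal 3 months 1 and 2 and of -2.52 in the other 3 libraries of that group.

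MHC class II genes were higher in the difference in 7 of 8 cases, 8 list-adjusted (camera adjusted p = 1.59e-07, 0.168 at estimated correlation). As a difference of responses, Cd74 stood at 2.10 ± 0.46 and H2-Ab1 at 2.13 ± 0.46. Interferon response genes were so in 8 of 20 cases, 16 list-adjusted (camera adjusted p = 7.84e-06, 0.361 at estimated correlation). Irf1 stood at 0.92 ± 0.20. Macrophage and monocyte markers were so in 4 of 14 cases, 13 list-adjusted (camera adjusted p = 2.23e-05, 0.361 at estimated correlation). Aif1 stood at 1.86 ± 0.41. T and NK cell markers were so in 4 of 14 cases, 4 also list-adjusted (camera adjusted p = 0.00626, 0.361 at estimated correlation). Lck stood at 2.07 ± 0.32. Endothelial markers were so in 4 of 11 cases, 5 list-adjusted (camera adjusted p = 0.0034, 0.361 at estimated correlation), neutrophil markers in 1 of 3, 3 list-adjusted (camera adjusted p = 0.0121, 0.168 at estimated correlation), and chemokine and cytokine genes in 5 of 14, 6 list-adjusted (camera adjusted p = 0.0207, 0.361 at estimated correlation). T and NK cell, endothelial and neutrophil lists had no call in either response (mean -0.84, -0.96 and -1.39 basal, 0.28, 0.19 and 0.83 luminal).

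Cell cycle genes were lower in the difference in 5 of 22 cases, 9 list-adjusted (camera adjusted p = 1.75e-05, 0.361 at estimated correlation). Mki67 stood at -1.87 ± 0.53 and Ube2c at -1.97 ± 0.45. Prostate secretory proteins were lower in 5 of 9 cases, 5 also list-adjusted (camera adjusted p = 0.000126, 0.168 at estimated correlation), with a larger fall in the luminal line (mean -4.09, and -0.31 in the basal line). Azgp1 stood at -2.83 ± 0.41 and Pbsn at -5.51 ± 1.17. Smooth muscle markers were lower in 1 of 12 cases, 3 list-adjusted (camera adjusted p = 0.000126, 0.361 at estimated correlation). Smtn stood at -1.46 ± 0.29. Unfolded protein response genes were lower in 4 of 15 cases, 5 list-adjusted (camera adjusted p = 0.000407, 0.361 at estimated correlation). Herpud1 stood at -1.66 ± 0.30. The list averaged 7.11 in luminal controls 1 and 2 but 8.26 and 7.77 in 5 and 6. Immediate early genes were lower in 5 of 12 cases, 6 list-adjusted (camera adjusted p = 0.000502, 0.361 at estimated correlation). Luminal tumours averaged 3.24 for the list, above luminal controls 1 and 2 and below 5 and 6, so both lists depend on the controls taken. Egr1 stood at -2.08 ± 0.50 and Ier2 at -0.83 ± 0.20. Progenitor-like and proximal luminal markers were lower in 5 of 13 cases, 5 also list-adjusted (camera adjusted p = 0.000851, 0.361 at estimated correlation), p53 and senescence genes in 5 of 13, 5 also list-adjusted (camera adjusted p = 0.000982, 0.168 at estimated correlation), and luminal cell markers in 4 of 10, 5 list-adjusted (camera adjusted p = 0.0176, 0.168 at estimated correlation). Squamous and keratinization genes were lower in 2 of 10 cases, 2 also list-adjusted (camera adjusted p = 0.0346, 0.361 at estimated correlation), and basal cell markers in 1 of 16, 1 also list-adjusted (camera adjusted p = 0.047, 0.507 at estimated correlation). Nkx3-1 differed by -2.09 ± 0.68 (adjusted p = 0.0347), a call that ended without any of basal 3 months 2, 3 or 4, luminal control 1, 2 or 5, or luminal 3 months 4, 5 or 6 (adjusted p between 0.0513 and 0.0791). Cd3d was at 2.32 ± 0.66 (adjusted p = 0.0162), and at 0.37 (adjusted p = 0.351) once values below 0 were raised to 0. A call of the MHC class II list ended in the same way (0.35, adjusted p = 0.339). Krt5 (-0.11 ± 0.28), Krt14 (-1.17 ± 0.47), Trp63 (0.11 ± 0.33), Krt8 (-0.43 ± 0.17), Krt18 (0.058 ± 0.13), Ar (0.11 ± 0.25), Pten (-0.081 ± 0.12), Serpine2 (-0.76 ± 1.42) and Spinkl (-1.74 ± 2.95) did not pass, though Krt8 passed with library weights (0.0417) or only the compared groups (0.00345) and Krt14 without luminal control 1 (0.036) or 2 (0.0234). Neither did Ctss (0.93 ± 0.42) or C1qa (1.02 ± 0.40), which both passed under several alternatives, for instance without luminal control 6 (1.29, adjusted p = 0.0274 for Ctss and 1.38, adjusted p = 0.0136 for C1qa). In total 2194 genes responded differently, 1184 more positively and 1010 more negatively in the luminal line, of which 623 and 433 by at least 2-fold, and 3400 with library weights. Among genes above the median level 552 were more positive and 684 more negative.

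Basal tumours at 6 months were compared with those at 3 months (n = 6 and 5), which follows this line over time and age. Lists of MHC class II genes and endothelial markers were higher at 6 months, and those of cell cycle and secretory genes lower, in camera calls lost at an estimated correlation. Olfm4 rose from -2.47 ± 1.36 to 4.75 ± 1.28, and the carboxylesterase gene Ces1d from 0.045 ± 1.59 to 5.13 ± 0.51. Igj, the joining chain of secreted antibodies, went from 0.20 ± 1.42 to 4.84 ± 1.26. Defb50, a defensin gene, fell from 11.37 ± 1.56 to 7.0 ± 0.92. Lce6a, of the cornified envelope, went from 3.82 ± 0.42 to -0.51 ± 0.78. Msmb went from 8.86 ± 1.57 to 4.74 ± 0.92.

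MHC class II genes rose in 7 of 8 cases, 8 list-adjusted (camera adjusted p = 4.47e-09, 0.112 at estimated correlation). Cd74 rose by 2.35 ± 0.31 and H2-Aa by 2.06 ± 0.32. Cell cycle genes fell in 17 of 22 cases, 18 list-adjusted (camera adjusted p = 1.59e-08, 0.213 at estimated correlation). Foxm1 changed by -1.89 ± 0.29, Top2a by -1.28 ± 0.22 and Mki67 by -1.78 ± 0.36. Endothelial markers rose in 10 of 11 cases, 10 also list-adjusted (camera adjusted p = 1.47e-07, 0.0865 at estimated correlation). Vwf rose by 2.35 ± 0.36 and Cdh5 by 1.89 ± 0.31. Complement and secreted defence genes rose in 8 of 11 cases and 1 fell, also list-adjusted (camera adjusted p = 1.03e-06, 0.0865 at estimated correlation). C3 rose by 3.00 ± 0.48. Macrophage and monocyte markers rose in 9 of 14 cases, 10 list-adjusted (camera adjusted p = 2.14e-06, 0.213 at estimated correlation). Lyz2 rose by 2.55 ± 0.50, Csf1r by 1.23 ± 0.24, Ctss by 1.20 ± 0.29 and C1qa by 1.10 ± 0.28. T and NK cell markers rose in 10 of 14 cases, 10 also list-adjusted (camera adjusted p = 3.03e-06, 0.154 at estimated correlation). Lck rose by 1.33 ± 0.22 and Cd8b1 by 2.50 ± 0.41. Neutrophil markers rose in 2 of 3 cases, 2 also list-adjusted (camera adjusted p = 0.00104, 0.0865 at estimated correlation), and B and plasma cell markers in 2 of 3, 3 list-adjusted (camera adjusted p = 0.00581, 0.193 at estimated correlation).

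Cholesterol synthesis genes fell in 10 of 18 cases, 11 list-adjusted (camera adjusted p = 0.000116, 0.317 at estimated correlation). Insig1 changed by -0.96 ± 0.21. Fibroblast and matrix genes rose in 5 of 15 cases, 5 also list-adjusted (camera adjusted p = 0.000437, 0.384 at estimated correlation). Thy1 rose by 2.58 ± 0.42. The list averaged 2.85 to 4.14 in basal 6 months 1, 2, 3 and 6 but 1.14 and 0.40 in 4 and 5, below the mean at 3 months (1.52). Mesenchymal transition genes rose in 3 of 9 cases, 4 rose and 1 fell list-adjusted (camera adjusted p = 0.0226, 0.213 at estimated correlation). Blood cell genes rose in 4 of 5 cases, 4 rose and 1 fell list-adjusted (camera adjusted p = 0.00565, 0.213 at estimated correlation), and ribosome biogenesis genes in 4 of 15, 4 also list-adjusted (camera adjusted p = 0.0357, 0.384 at estimated correlation). Prostate secretory proteins fell in 4 of 9 cases, 5 list-adjusted (camera adjusted p = 0.00356, 0.206 at estimated correlation), and squamous and keratinization genes in 5 of 10, 5 also list-adjusted (camera adjusted p = 0.0273, 0.213 at estimated correlation). Luminal cell markers fell in 5 of 10 cases, 5 fell and 1 rose list-adjusted (camera adjusted p = 0.0273, 0.154 at estimated correlation). Nkx3-1 changed by -2.67 ± 0.47. Of 13 p53 and senescence genes 4 fell and 1 rose, 6 and 1 list-adjusted (camera adjusted p = 0.0287, 0.213 at estimated correlation). Cd3d rose by 1.62 ± 0.44, but by 0.39 (adjusted p = 0.0931) once values below 0 were raised to 0. Pbsn (-1.68 ± 0.79), Krt14 (0.20 ± 0.32), Trp63 (-0.17 ± 0.23), Krt8 (-0.065 ± 0.12), Ar (-0.038 ± 0.17), Pten (-0.057 ± 0.080), Spinkl (4.60 ± 2.02) and Serpine2 (-0.24 ± 0.97) did not pass. Spinkl passed without basal 6 months 6 (5.88, adjusted p = 0.0291), Pbsn with library weights (0.0396) and Serpine2 without the vesicle-high libraries (-2.24, adjusted p = 0.00168). Krt5 (-0.44 ± 0.19, adjusted p = 0.0942) passed with library weights (-0.78, adjusted p = 0.00161) and without basal 3 months 2 or basal 6 months 1 or 2 (adjusted p = 0.0388, 0.00938 and 0.0268), and Krt18 (-0.16 ± 0.092) passed after quantile normalization (-0.24, adjusted p = 0.0307). The comparison called 3582 genes, 1562 higher and 2020 lower at 6 months, of which 782 and 540 differed at least 2-fold.

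Luminal tumours at 3 months were compared with those at 1 month (n = 6 each), which follows the luminal line over time and age. The list of glycolysis and hypoxia genes was higher at 3 months, and those of smooth muscle and unfolded protein response genes lower by camera, but not at an estimated correlation. The spermine-binding protein gene Sbp rose from 3.39 ± 2.00 to 10.16 ± 1.59, and its near copy Sbpl, with which it may share reads, from 1.76 ± 1.97 to 8.72 ± 1.59. Adm, the hypoxia-induced adrenomedullin gene, went from 0.58 ± 0.57 to 3.05 ± 0.39. Clec2e fell from 5.13 ± 0.67 to -1.41 ± 0.45. Gpx3, a secreted glutathione peroxidase gene, went from 8.82 ± 2.20 to 4.73 ± 0.56, with a mean of 10.79 in libraries 1 to 3 and 6.85 in 4 to 6 at 1 month. Des, the desmin gene of muscle, went from 4.89 ± 1.38 to 1.61 ± 1.51.

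Glycolysis and hypoxia genes rose in 12 of 17 cases, 13 list-adjusted (camera adjusted p = 9.4e-09, 0.309 at estimated correlation). Egln3 rose by 2.24 ± 0.32 and the glucose transporter gene Slc2a1 by 0.90 ± 0.13. Unfolded protein response genes fell in 11 of 15 cases, 12 list-adjusted (camera adjusted p = 1.2e-07, 0.55 at estimated correlation). Hyou1 changed by -0.89 ± 0.15 (n = 5 at 3 months). Smooth muscle markers fell in 7 of 12 cases, 11 list-adjusted (camera adjusted p = 4.73e-06, 0.645 at estimated correlation). At 1 month the list averaged 3.27 to 4.54 in 4 libraries, but 1.70 and 1.83 in libraries 4 and 6, within the range at 3 months (0.083 to 2.27). Acta2 changed by -2.39 ± 0.67. Fibroblast and matrix genes fell in 2 of 15 cases, Postn by 2.99 ± 0.62 and Fn1 by 2.36 ± 0.53, 2 also list-adjusted (camera adjusted p = 0.0139, 0.645 at estimated correlation). Of 22 cell cycle genes 3 fell, 1 list-adjusted (camera adjusted p = 0.0152, 0.645 at estimated correlation). Top2a changed by -0.75 ± 0.21. Of 15 ribosome biogenesis genes 1 fell, Nolc1 by 0.37 ± 0.095, 1 also list-adjusted (camera adjusted p = 0.0181, 0.645 at estimated correlation). T and NK cell markers rose in 3 of 14 cases, 4 list-adjusted (camera adjusted p = 0.0263, 0.645 at estimated correlation). Lck rose by 1.04 ± 0.21. Krt5 fell by 0.64 ± 0.19. Pten changed by -0.30 (adjusted p = 0.00525) and Nkx3-1 by -1.56 (adjusted p = 0.0137), calls that ended once luminal control 6, luminal 1 month 2 and luminal 3 months 5 were left out together (adjusted p = 0.0512 and 0.091), and for Nkx3-1 without luminal 1 month 2 alone (-1.26, adjusted p = 0.0507). At 1 month Nkx3-1 was 3.67 to 4.48 in libraries 1 to 3 and 1.54 to 2.113 in 4 to 6. Krt14 (-0.39 ± 0.31), Trp63 (-0.44 ± 0.22), Krt8 (0.012 ± 0.11), Krt18 (-0.015 ± 0.087), Ar (0.11 ± 0.17), Pbsn (-0.25 ± 0.79), Ctss (0.47 ± 0.27), C1qa (0.33 ± 0.26), Cd3d (0.76 ± 0.44) and Spinkl (1.11 ± 1.92) did not pass, though Ctss did with only the compared groups (0.0489). Neither did Serpine2 (-2.20 ± 0.93), which passed without luminal 1 month 4 (adjusted p = 0.044) or luminal 3 months 5 (adjusted p = 0.0404), with library weights (0.0233) and without the vesicle-high libraries (0.000985), or Mki67 (-0.76 ± 0.35, adjusted p = 0.122), which passed after quantile normalization (-0.95, adjusted p = 0.0316), with library weights (0.0236), with only the compared groups (0.0319) and with values below 0 raised to 0 (0.0373). The comparison called 2690 genes, 1360 higher and 1330 lower at 3 months, of which 234 and 251 differed at least 2-fold. With each library centred on its median, 984 were higher and 1758 lower.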

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

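The tests of a tumour library under a control label and of a difference the lines have without induction were chosen after the result was seen.

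The difference between the responses at 3 months called 2194 genes. Among genes named here, the luminal response was the more positive for Ifi202b (5.88), Olfm4 (4.98), Muc20 (3.85), Aim2 (3.68), Cd3d (2.32), H2-Ab1 (2.13), Cd74 (2.10), Lck (2.07), Aif1 (1.86), H2-DMa (1.66), Csf1r (1.02) and Irf1 (0.92). It was the more negative for Camk2b (-12.67), Msmb (-10.40), Clec2e (-7.71), Glb1l3 (-6.01), Pbsn (-5.51), Tgm4 (-4.84), Azgp1 (-2.83), Nkx3-1 (-2.09), Egr1 (-2.08), Ube2c (-1.97), Birc5 (-1.92), Mki67 (-1.87), Herpud1 (-1.66), Smtn (-1.46), Nr4a1 (-1.23), Sdf2l1 (-1.08), Ier3 (-0.97) and Ier2 (-0.83). The call of Csf1r ended after quantile normalization, median centring and with no trend (adjusted p = 0.0522, 0.0603 and 0.057) and without any single library but basal control 4, basal 3 months 5, luminal control 5 or 6 or luminal 3 months 6 (0.0536 to 0.117). Calls also ended for Birc5 without luminal control 6 (0.067), for Nr4a1 without luminal control 5 (0.0714), for Olfm4 once values below 0 were raised to 0 (0.137), and for Nkx3-1 and Cd3d as given above. Between the times of a line, 3582 genes differed for basal tumours at 6 and 3 months and 2690 for luminal tumours at 3 and 1 months. In each of the 9 comparisons the real grouping was the only 1 of 100 groupings of the same libraries with as many calls, so a chance division of the libraries was excluded at that number. In the order of the Results, the highest of the other groupings gave 8330, 7226, 6342, 6180, 2157, 707, 1174, 2046 and 433 calls.

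Immune lists were higher in luminal than in basal tumours at 3 months by camera, but not with estimated correlation (adjusted p = 0.174, 0.346 and 0.174 for MHC class II, macrophage and T and NK cell lists). For MHC class II genes the response was 122.2% of the difference between the tumours (more than 2 SE above a share of 0.5, without luminal 3 months 5). This argues against a difference the lines have without induction as the larger part. Basal controls parted (3.27 to 4.00 in 1 to 3, 1.76 to 2.68 in 4 to 6), so it is not excluded. Macrophage (111.3%) and T and NK cell markers (65.15%) lay within 2 SE of that share. Luminal tumours at 3 months may resemble basal ones at 6 months. Their squared distance per gene was 0.233, and 0.440 to basal tumours at 3 months. The ratio of 0.530, just above the bound of 0.5 set beforehand, does not tell it from a difference of origin. The correlation of both differences across genes (0.552) decides nothing: whatever sets basal tumours at 3 months apart enters both, despite separate libraries. Time in the tumour, cell of origin and Cre line (Nkx3-1 allele, share of cells recombined) stay open. So do differences without induction, less so for MHC class II genes.

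Luminal control 6 lay toward the tumours, with macrophage markers 1.42 and progenitor-like markers 1.07 above the other 3 luminal controls. Seminal vesicle (1.98), adipocyte (1.46) and urothelial genes (1.04) and, away from the tumours, secretory proteins (1.89) were higher too. A tumour library under a control label was excluded. Control 6 had a place of 0.212 between the other luminal controls (0) and luminal tumours at 3 months (1). More leukocytes alone stay open: the progenitor-like mean lay 0.724 above the highest of only 3 others (5.15 to 5.76). Genes 16-fold lower in tumours shifted by -0.467 beyond what a mixed-in 2.62% of luminal tumour at 3 months allows. They were picked by the other luminal controls, which alone can put control 6 lower, so mixing stays open. An earlier lesion, another prostate part or a neighbouring tissue may be present, which list shifts do not separate.

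In 52 cases, covering 47 genes, some libraries of a group held a gene at a level at least 3 log2 units above the rest, such as Gdpd3, high in luminal libraries 1 to 3 and low in 4 to 6 at 1 and at 3 months. Inherited segments that differ between animals remain open, since 15.7% of cases had another case within 3 places in the gene order, above the highest of 1000 random draws (7.84%), but 3.92% once genes of the same name stem were left out. Another tissue or lobe in some pieces remains open as well, since 73.9% of cases parted their libraries as 1 of 6 lists of other tissues did, where 53.8% would by chance. With these values the explanations cannot be told apart.

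Among 690 pairs of a named gene and a group, 47 had 1 library whose gap to the next, divided by the group's range, was unusually wide, where chance gives about 1 in 20 groups. In basal 3 months 5 these were Aass (0.749), C1rb (0.802), Gdpd3 (0.722), Glb1l3 (0.720), Irf1 (0.756), Irf7 (0.768), Nos2 (0.843), Padi4 (0.722) and Rtp4 (0.736). Basal control 1 stood apart for Gsdma2 (0.642), Krt6a (0.628), Nos2 (0.696), Nupr1 (0.809), Pglyrp1 (0.649), Pigr (0.687), Sbpl (0.775), Slco1a5 (0.707) and Wfdc2 (0.7103). In luminal 1 month 4 these were Birc5 (0.629), Igj (0.702), Krt14 (0.735), Krt15 (0.714), Krt18 (0.633), Krt8 (0.666) and Sbpl (0.667). Basal control 4 stood apart for Adm (0.707), Csf1r (0.722), Ifi202b (0.631), Krt7 (0.642) and Mrc1 (0.628). In basal 6 months 3 these were Nr4a1 (0.757), Pkm2 (0.6252), Sdf2l1 (0.680) and Slco1a5 (0.665). Basal control 6 stood apart for Des (0.642) and Thy1 (0.742). In luminal 3 months 3 these were Herpud1 (0.720) and Hyou1 (0.803). Single genes were Slc2a1 in basal 6 months 2 (0.693), Gbp2 in basal control 5 (0.666), Mcoln3 in basal 6 months 6 (0.645), Gzmb in basal 3 months 1 (0.719), Nolc1 in luminal 1 month 2 (0.722), Spinkl in luminal 1 month 5 (0.779), Serpine2 in luminal 3 months 5 (0.634), Top2a in luminal control 2 (0.886) and Postn in luminal control 5 (0.958).

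Spinkl averaged 12.72 in basal 6 months 2 and 3 and 4.43 in the other 4 libraries of that group. The misplaced values of luminal 3 months 5 (1777 lines) were not used.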

How the results depend on the processing

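The fit of all 34 libraries is the planned one. Leaving out luminal control 4 or doubted libraries was chosen after seeing the data. So were the tests with the misplaced values kept, values below 0 raised to 0 and a mean of at least 0. Of 522 gene results named by the rule, 436 passed the threshold, 308 of these under every alternative run, and 12 were reversed under one. No filter gave the same calls by construction, since the planned filter removed 0 genes, and a smaller pseudocount was not run because the values were already logarithms. For the other alternatives the cause was not tested, except where stated.

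With only genes above the median level, which tests fewer genes, the calls were 5134 and 5390 for basal tumours at 3 and 6 months, 5097 and 5176 for luminal tumours at 1 and 3 months, 2529 between the tumours at 3 months, 1236 for the difference between responses and 1773 between basal tumours at 6 and 3 months. Library weights gave 6927 calls between the tumours at 3 months and 3400 for the difference between responses. With all 34 libraries, luminal control 4 on its own scale and with its misplaced values, the calls were 4572 and 5259 for basal tumours at 3 and 6 months, 1009 between the tumours at 3 months, 1054 between the controls, 667 for the difference between responses, 1179 between basal tumours at 6 and 3 months and 297 between luminal tumours at 3 and 1 months. That library ended 97 calls among genes named by the rule and reversed Pfkl (-0.94), Pgam1 (-0.93) and Krt18 (-0.71) in luminal tumours at 1 month and Pfkl (-0.45), Pgam1 (-0.72), Krt14 (-0.13) and Krt18 (-0.73) at 3 months. It reversed Fdft1 (1.17) and Nop56 (-0.057) between the controls and Usp18 (-1.64) in the difference between responses. Quantile normalization reversed Krt18 in basal tumours at 6 months (-0.29), and the misplaced values of luminal 3 months 5 ended 18 such calls and reversed Ar in luminal tumours at 3 months (-0.13). Between luminal tumours at 3 and 1 months, 1360 higher and 1330 lower genes turned to 984 and 1758 with median centring, 1204 and 1501 with quantile normalization and 707 and 1094 above the median level.

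Leaving out each library in turn gave 8867 to 9130 calls for basal tumours at 3 months, 9640 to 9869 at 6 months, 8496 to 9057 for luminal tumours at 1 month, 8709 to 9147 at 3 months, 3263 to 4150 between the tumours at 3 months, 1737 to 2428 for the difference between responses, 2681 to 3915 between basal tumours at 6 and 3 months and 2065 to 2724 between luminal tumours. Between the controls it gave 1481, without luminal control 6, to 2488. Of the lists called, the estimated correlation kept 1 for basal tumours at 3 months and 0 in each other comparison. With fry, which does not compare a list with other genes, 25 and 24 lists passed for basal tumours at 3 and 6 months, 19 and 21 for luminal tumours at 1 and 3 months and 5 between the controls. Quantile normalization called 12 lists between luminal tumours at 3 and 1 months. Genes called in both lines and changed at least 2-fold in the same direction numbered 2928.

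Whether replicate numbers mark a batch is not settled. Over 75 pairs of libraries with the same number in different groups the median correlation was 0.0357 (-0.379 to 0.546), 23 lay above 0.1, the median over 377 pairs with different numbers was -0.00678, and for 11 of 33 libraries the best partner had the same number. At 1 month luminal libraries 1 to 3 all lay above 4 to 6 for Pten, Nkx3-1, Pbsn, Gpx3, Gdpd3, Trp63 (4.63 to 4.66 and 3.63 to 4.03) and secretory proteins (4.57 to 5.42 and 3.48 to 4.30). Basal 6 months 1 to 3 lay above 4 to 6 for Trp63 (4.14 to 4.35 and 3.30 to 3.801) and Krt14 (6.65 to 7.37 and 5.83 to 6.02) and below for interferon response genes (4.87 to 5.70 and 6.34 to 7.15), and all 6 two-level genes of basal controls parted this way. With the number as a block the calls were 9210, 9903, 9019, 9220, 4013, 2367, 2128, 3497 and 2681, in the order of the Results. Among genes named by the rule the block ended 6 calls and added 2. The depth is unknown, so genes near or below 0 carry the least certain changes.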

Other observations

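No test in this part was chosen after the result was seen. Genes that respond to androgen went both ways in all 4 comparisons of tumours with controls. Of 14 such genes, 5 rose and 4 fell in basal tumours at 3 months (camera adjusted p = 0.588), 7 rose and 5 fell at 6 months (camera adjusted p = 0.411), 7 rose and 4 fell in luminal tumours at 1 month (camera adjusted p = 0.56), and 7 rose and 5 fell at 3 months (camera adjusted p = 0.668). List-adjusted counts were the same. The test pointed up in each, whereas the mean was -0.063, -0.26 and -0.37 in the last 3. FOXO target genes, which FOXO factors switch on where AKT is not active, went both ways at 3 months. In basal tumours 8 of 16 fell and 4 rose (camera adjusted p = 0.604). In luminal tumours 6 fell and 5 rose (camera adjusted p = 0.979), also list-adjusted. Of 15 oxidative phosphorylation genes 6 rose and 1 fell in basal tumours (camera adjusted p = 0.182). In luminal tumours at 3 months 7 rose and 2 fell (camera adjusted p = 0.166), again also list-adjusted.

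Lists of tissues that border the prostate gave no call with camera (lowest adjusted p = 0.054, adipocyte genes between luminal tumours at 3 and 1 months), though single members passed: of 5 urothelial markers 3 rose and 1 fell in basal tumours at either time. With fry, adipocyte genes passed upward for basal tumours at 3 and 6 months, luminal tumours at 1 month and between basal tumours (adjusted p = 0.00317, 1.46e-06, 0.000297 and 0.00775; 1 of 3 members rose in each, and 1 fell at 1 month) and downward between luminal tumours (0.000521). Urothelial markers did so upward for basal tumours at 6 months (0.00286) and skeletal muscle genes downward for luminal tumours at 3 months (0.0385). Urothelial markers averaged 1.70 ± 0.36 in basal controls, 2.70 ± 0.47 in basal tumours at 3 months, 2.33 ± 0.53 in luminal controls and 3.1 ± 0.30 in luminal tumours at 3 months. Skeletal muscle genes averaged 2.04 ± 0.38 in luminal controls and 0.67 ± 1.06 in luminal tumours at 3 months, and adipocyte genes -0.62 ± 0.20 in basal controls and 0.88 ± 0.68 in basal tumours at 6 months. The 3 seminal vesicle genes averaged 2.98 ± 0.38 in basal controls and 6.25 ± 4.20 in basal tumours at 6 months. Neuroendocrine markers, of which 4 were measured, averaged 0.062 ± 0.43 in basal controls and -1.20 ± 0.44 in basal tumours at 3 months.

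Over 3876 genes the SD of the difference between luminal 1 month 1 and 3 was 0.165, where the median pair of that group had 0.414. No pair had identical values (0% of genes).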
